A study of Mus musculus with 14 samples.

How the data were processed

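Lungs of C57BL/6 mice were enzymatically dissociated and profiled by droplet-based single-cell RNA sequencing with 3' v3 chemistry from 10x Genomics. Cell suspensions were stained with TotalSeqA hashtag antibodies, which mark the animal a cell came from, before 2 mice were combined in each library. Mice either had no tumor or carried the M3-9-M tumor, a mouse rhabdomyosarcoma line, and were sampled before lung metastasis. Part of each arm received IL12-GEMys, myeloid cells engineered to make interleukin-12. The labels list 7 libraries, each with a gene expression and a hashtag part. They comprise 2 libraries of untreated tumor-free mice, 1 of tumor-free mice given IL12-GEMys, 2 of untreated tumor-bearing mice and 2 of tumor-bearing mice given IL12-GEMys.

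The deposited matrices hold raw UMI counts per gene and cell barcode for 31053 genes, with the counts of 4 hashtag antibodies as the last features of each matrix. Cell Ranger 3.0.2 and the genome build mm10 are named in the submitters' processing notes. The gene annotation the authors counted against and their parameters are not given in the sources used here. The matrices are filtered ones, and the lowest barcode total in any library was 500 UMIs. No cell type annotation was used from the authors, so the names were rebuilt for 22 classes. Gene coordinates were taken from GENCODE vM21 on the same build, which covered 99.6% of the genes by identifier. Whether the interleukin-12 transgene of the engineered cells would align to the reference is not stated, so endogenous and engineered Il12a and Il12b cannot be separated here.

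Of 99380 barcodes, 79821 passed limits of at least 500 UMIs, at least 200 genes and at most 15% mitochondrial UMIs. Doublets were called from the hashtags (both of a library's 2 most counted hashtags above an Otsu threshold on logged counts) and from neighbors, where more than 30% of a cell's 50 nearest neighbors were hashtag doublets. This removed 6.94% to 10.4% of cells per library and left 72551. Doublets of 2 cells from the same animal are seen only by the neighbor step. Counts were scaled to 10000 per cell and logged, 2000 variable genes were reduced to 30 principal components, and a graph of 15 neighbors was clustered with the Leiden algorithm at resolution 1 into 40 clusters, without batch integration. A class's score in a cluster was the mean over its markers of log2 of the cluster's CPM plus 5 over the mean CPM of the 40 clusters plus 5. Clusters whose second-best class also scored above 1, or that scored at least 1 but met another reason to stay unnamed, were divided again at resolution 0.5, giving 105 clusters. A cluster was called X-like from marker lists fixed before the data were examined, where its mean log2 marker score was at least 1, the second-best class scored at most 0.6 of it, at least 3 markers were detected in more than 10% of cells, hashtag doublets made up at most 15% and the 10 leading genes held no more markers of another class than of its own. The scoring limits themselves were set after the data were seen. They left 3969 cells (5.47%) unnamed: a mean of 3.50% of cells in untreated tumor-free, 3.83% in treated tumor-free, 6.91% in untreated tumor-bearing and 6.84% in treated tumor-bearing libraries.

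UMI counts were summed per library and class, using only libraries with at least 30 cells of the class, and tested with edgeR quasi-likelihood (glmQLFit with robust fitting and glmQLFTest, TMM scaling, filterByExpr) in one model of the 4 groups over all 7 libraries. P-values were adjusted by the Benjamini-Hochberg method within each class, with a threshold of 0.05. The replicate is the library, a pool of 2 mice, because the labels list libraries. P-values therefore measure the spread between 2 pools per group, with the single treated tumor-free library assumed to vary like the others. Levels are TMM-scaled CPM of the class's summed UMIs, not shares of UMIs, as mean ± SD over libraries. Errors of log2 folds are standard errors (SE). Cell shares were tested with edgeR quasi-likelihood (legacy fit, library size equal to the cells kept, no TMM), adjusted over the 22 classes. A permutation of 2 against 2 libraries cannot give a p below 0.33, so no permutation test of these comparisons was made.

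The main comparisons were tumor-bearing against tumor-free mice without treatment, and IL12-GEMy against no treatment in tumor-bearing mice, in 6 classes (T, NK, classical monocyte, neutrophil, alveolar macrophage and endothelial). Another 6 classes were fitted the same way. For the treatment without tumor and for the difference between the treatment effects with and without tumor, values are given for named genes and lists only. The design, the alternatives, 19 gene lists and the rule for named genes were fixed before the data were examined. That rule took, per class and comparison, the 3 largest rises and 2 largest falls among genes past the threshold. They needed a mean of at least 20 CPM, libraries of the groups that did not overlap, and a level of at least 10% of that in the gene's highest class. Hemoglobin, immunoglobulin, mitochondrial, predicted and sex-linked genes were left out. The rule also took the members with the smallest adjusted p of each list described, and gave Il12a, Il12b, Ifng, Cxcl9, Cd274, Arg1, S100a8 and S100a9 in every case, and 1 more gene that is not reported here. Lists with at least 4 tested members were tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over lists and classes, and again with an estimated correlation and with fry. Where a group held 1 to 3 UMIs of a gene, its ratio is given with a 95% counting interval over the summed UMIs. Where it held 0, the ratio is a lower bound against a floor of 3 UMIs over the group. Both cover counting error only.

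The gene test was first tested on simulated data: counts were drawn for the real genes at the real library sizes and 200 genes were changed by known folds, in 5 draws per class and comparison. For tumor against no tumor, the test recovered 74.2% of 2-fold changes in T cell-like cells, 67.3% in NK cell-like cells, 65.1% in classical monocyte-like cells, 42.1% in neutrophil-like cells, 71.5% in alveolar macrophage-like cells and 16.9% in endothelial cell-like cells. For the treatment in tumor-bearing mice the same shares were 76%, 78.9%, 78.3%, 58%, 68.2% and 14.5%. Changes of 4-fold were recovered in 69.8% to 96.7% of cases. The share of false calls was 6.3% to 11.2%, above the nominal 5%.

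Alternatives tried were DESeq2's size factors in edgeR, DESeq2 itself, no low-count filter, only the 4 libraries compared, each library left out, the animal numbers as a block, animals as replicates through their hashtags, doublets kept, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial UMIs), Leiden resolution 2, TMM over classes, immune classes only and the other list tests. Values of members of near-identical families, such as Gbp, H2-Q, Serpina3, Tgtp, Ifit3 and hemoglobin genes, are uncertain, since how shared reads were counted is not given in the sources used here. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Hashtags were used only for doublets and for the values per animal, since the labels do not say which hashtag marks which animal.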

Results

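The 7 libraries, each a pool of 2 mice, held 99380 cell barcodes. Untreated tumor-free mice gave 2 libraries with 17400 and 12676 barcodes and 53824025 and 45064016 UMIs. The single library of tumor-free mice given IL12-GEMys had 12656 barcodes and 64095352 UMIs. Untreated tumor-bearing mice gave 2 libraries with 13886 and 11604 barcodes and 63667102 and 59199351 UMIs. Tumor-bearing mice given IL12-GEMys gave 2 libraries with 17630 and 13528 barcodes and 87211520 and 82668834 UMIs. After filtering, 72551 cells remained. The median was 2670 and 3065 UMIs per cell in the untreated tumor-free libraries and 4007 in the treated tumor-free library. It was 3635 and 3832 in the untreated and 3940 and 4570 in the treated tumor-bearing libraries. Of these cells, 68582 fell in 22 named classes. Errors of levels are SDs over the 2 libraries of a group, and the treated tumor-free group has no SD.

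The first comparison addresses what a tumor elsewhere changes in lungs without metastases, the second what IL12-GEMys change in tumor-bearing lungs. The treated tumor-free library describes the treatment without a tumor and lets both treatment effects be compared.

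Neutrophil-like cells took a larger share of untreated tumor-bearing lungs. They made up 5.75% ± 0.245 of cells without tumor and 34.9% ± 6.31 with tumor (n = 2 libraries each), a log2 change of 2.60 ± 0.32 (SE). Classical monocyte-like cells rose from 3.96% ± 0.350 of cells to 12.1% and 9.83% in the libraries with tumor, a log2 change of 1.47 ± 0.30. B cell-like cells fell from 37.4% ± 2.50 to 11.6% ± 4.10, a log2 change of -1.69 ± 0.35. T cell-like cells made up 21.0% ± 1.06 of cells without and 12.6% ± 0.931 with tumor. NK cell-like cells made up 11.6% ± 0.067 and 7.08% ± 0.645. Among 22 classes, neutrophil-like (adjusted p = 0.00297), B cell-like and classical monocyte-like cells (adjusted p = 0.0183 for both) passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. T cell-like (adjusted p = 0.125) and NK cell-like cells (adjusted p = 0.151) did not pass the edgeR test. The B cell call was lost without untreated tumor-bearing library 1 (-1.37, adjusted p = 0.113, edgeR). The monocyte call was lost without untreated tumor-free library 1 (1.38, adjusted p = 0.199) or 2 (1.56, adjusted p = 0.075) or untreated tumor-bearing library 1 (1.31, adjusted p = 0.113) in the same edgeR test. Without the last, 1 class passed in place of 3.

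**Figure D1:**
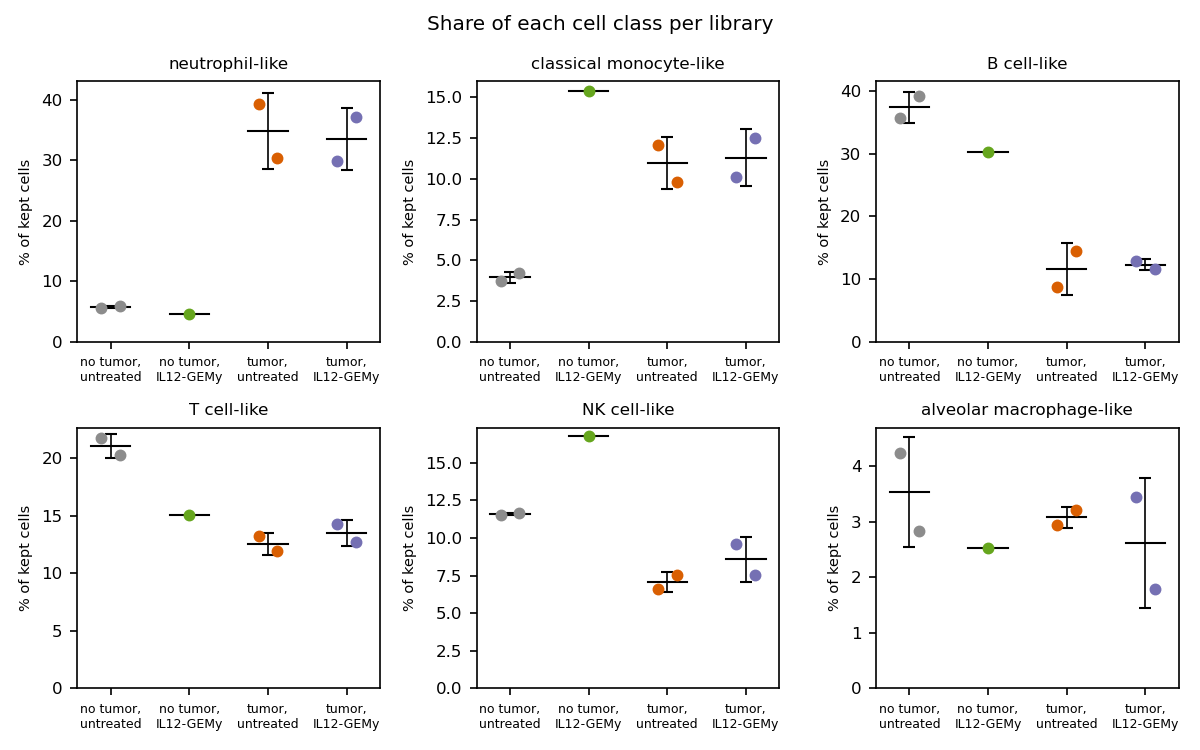
Share of kept cells, in percent, for 6 classes in each library (points), with the mean (line) and SD (error bar) of each group. The neutrophil-like share lies at 5.75% on average in untreated tumor-free libraries and at 34.9% in untreated tumor-bearing ones.

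T cell-like cells of untreated tumor-bearing lungs held more RNA of cytotoxic effector and inhibitory receptor genes. Gzmk, a granzyme of effector memory cells (ENSMUSG00000042385, mm10 chromosome 13, 113171608 to 113225908), rose from 8.14 ± 3.70 to 58.2 ± 13.6 CPM, with a log2 fold of 2.89 ± 0.32. Gzmb, a cytotoxic granule protease (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), rose from 39.3 ± 6.86 to 276 ± 66.2 CPM. Pdcd1, which encodes the inhibitory receptor PD-1, rose at 2.76 ± 0.37 on the log2 scale, from 3.39 ± 0.42 CPM. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 1194 of 11557 genes changed, 841 of them upward. The adjusted p (edgeR) was 0.00441 for Gzmk, 9.83e-04 for Gzmb and 0.00444 for Pdcd1. The count was 499 without untreated tumor-free library 1 and 384 without library 2. The make-up of the class moved too, as clusters 18 and 23, both partly defined by Gzmk, held 5.1% and 1.2% of it without and 21.3% and 5.3% with tumor.

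Among the fixed lists in T cell-like cells, 15 of 18 proliferation genes rose (18 adjusted over the list alone). Of 17 cytotoxic effector genes 12 rose (13 adjusted over the list alone). Of 8 inhibitory receptors 4 rose (5 adjusted over the list alone), including Havcr2, which encodes TIM-3, at 3.38 ± 0.37. These 3 lists had an adjusted p = 0.206 with an estimated correlation in camera. Genes of naive and memory T cells fell in 3 of 10 cases (5 adjusted over the list alone; adjusted p = 0.371 with an estimated correlation). Among them were Lef1 at -0.62 ± 0.13 and S1pr1, the receptor for exit from lymphoid organs, at -0.53 ± 0.11. Type I interferon response genes rose in 9 of 19 cases (12 adjusted over the list alone; adjusted p = 0.295 with an estimated correlation). Of 23 interferon gamma response genes 7 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.371 with an estimated correlation). Glycolysis and hypoxia genes rose in 7 of 14 cases (9 adjusted over the list alone; adjusted p = 0.299 with an estimated correlation). Of 12 genes of interleukin-12 and interleukin-18 signalling 3 rose, also when adjusted over the list alone (adjusted p = 0.316 with an estimated correlation).

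Further lists moved in T cell-like cells together with S100a8, a transcript abundant in neutrophil-like cells. S100a8 UMIs averaged 0.328 and 0.552 per T cell-like cell in the untreated tumor-free libraries and 10.6 and 5.14 in the untreated tumor-bearing ones. Cxcl2 and Mmp9 stood at 0.978% and 0.667% of their level in their highest class. Pre-metastatic niche genes rose in 8 of 14 cases (10 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation). Myeloid suppression genes rose in 8 of 19 cases, also when adjusted over the list alone (adjusted p = 0.206 with an estimated correlation). TNF and NF-kB targets rose in 3 of 12 (also 3 adjusted over the list alone; adjusted p = 0.284 with an estimated correlation) and neutrophil granule genes in 1 of 10 (also 1 adjusted over the list alone; adjusted p = 0.322 with an estimated correlation). MHC class II genes fell in 7 of 11 cases (8 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation) while the B cell-like share fell. The members with the smallest adjusted p stood at or below 3.54% of their highest class.

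NK cell-like cells of tumor-bearing lungs held more RNA of cell division genes. Hmmr, a spindle protein, rose from a mean of 0.831 to 10.7 ± 2.64 CPM (log2 fold 3.59 ± 0.45), and Tk1, the thymidine kinase of S phase, from 1.89 to 12.7 ± 0.792 CPM. Emb, a cell surface glycoprotein, fell from 303 ± 9.85 to 129 ± 23.4 CPM. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 486 of 10652 genes changed, 327 upward, with an adjusted p = 1.63e-05 for Hmmr and Tk1 and 5.82e-06 for Emb. The count was 139 without untreated tumor-free library 1, 175 without library 2 and 1044 without untreated tumor-bearing library 1. Cluster 21, which Top2a and Mki67 help define, held 0.6% of the class without and 3.2% with tumor.

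Of 18 proliferation genes 13 rose in NK cell-like cells (16 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation). Mki67 rose from 18.7 ± 0.602 to 72.4 ± 0.389 CPM. Cytotoxic effector genes rose in 7 of 17 cases (8 adjusted over the list alone; adjusted p = 0.295 with an estimated correlation). Gzmb rose from 823 ± 51.3 to 1659 ± 224 CPM. Naive and memory genes fell in 4 of 10 cases (6 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation). Immediate-early genes of dissociation stress fell in 4 of 15 cases (7 adjusted over the list alone; adjusted p = 0.336 with an estimated correlation). This call was lost without untreated tumor-free library 1 (adjusted p = 0.102, camera). Glycolysis genes rose in 5 of 14 cases with 1 fall (7 and 2 adjusted over the list alone; adjusted p = 0.295 with an estimated correlation). That call was lost without untreated tumor-free library 1 (adjusted p = 0.102, camera) or 2 (adjusted p = 0.0793, camera). S100a8 averaged 0.291 and 0.545 UMIs per NK cell-like cell without tumor and 12.4 and 5.21 with tumor. Together with it, neutrophil granule genes rose in 5 of 10 cases, also when adjusted over the list alone (adjusted p = 0.284 with an estimated correlation). Niche genes rose in 2 of 13 (8 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation) and myeloid suppression genes in 4 of 18 with 1 fall (6 and 2 adjusted over the list alone; adjusted p = 0.347 with an estimated correlation). MHC class II genes fell in 1 of 11 cases (4 adjusted over the list alone; adjusted p = 0.347 with an estimated correlation), a call lost without untreated tumor-bearing library 1 (adjusted p = 0.127, camera).

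In neutrophil-like cells 2072 of 10595 genes passed the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment, 1326 of them upward. Wfdc17, a gene of activated myeloid cells with a protease inhibitor domain (ENSMUSG00000069792, mm10 chromosome 11, 83703991 to 83706268), rose from 482 ± 147 to 18383 ± 4178 CPM, a log2 fold of 5.25 ± 0.32 (adjusted p = 5.18e-09, edgeR). Camp, the cathelicidin of secondary granules (ENSMUSG00000038357, chromosome 9, 109847379 to 109849617), fell from 6041 ± 1691 to 1170 ± 406 CPM, a log2 fold of -2.37 ± 0.28 (adjusted p = 2.44e-05, edgeR). The count of genes was 1196 without untreated tumor-free library 1, 1035 without library 2 and 1148 without untreated tumor-bearing library 1. Different clusters held most of the class without tumor (cluster 11, 84.4%) and with tumor (cluster 2, 81.6%). The median UMI count per neutrophil-like cell was 1416 and 1626 without and 3213 and 2928 with tumor.

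The alarmins S100a8 and S100a9 rose in neutrophil-like cells, S100a8 from 65262 ± 10186 to 200259 ± 38456 CPM and S100a9 from 55015 ± 7412 to 160292 ± 12630 CPM. They belong to the niche list, in which 10 of 15 genes rose and 2 fell (the same numbers adjusted over the list alone; adjusted p = 0.284 with an estimated correlation). Of 14 glycolysis and hypoxia genes 10 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.295 with an estimated correlation). Of 18 type I interferon response genes 12 rose (15 adjusted over the list alone; adjusted p = 0.295 with an estimated correlation). Interferon gamma response genes rose in 9 of 25 (11 adjusted over the list alone; adjusted p = 0.284 with an estimated correlation) and MHC class I genes in 9 of 17 (10 adjusted over the list alone; adjusted p = 0.486 with an estimated correlation). Myeloid suppression genes rose in 10 of 19 cases and fell in 4 (11 and 4 adjusted over the list alone; adjusted p = 0.356 with an estimated correlation). The receptor gene Il4ra stood at 1.98 ± 0.20 and the NADPH oxidase subunit gene Cybb at -1.37 ± 0.21. The granule list was not called, as 4 of its 11 genes rose and 5 fell. Ly6g rose at 1.70 ± 0.24, while the secondary granule genes Ngp and Ltf fell at -1.30 ± 0.21 and -1.65 ± 0.27. MHC class II genes fell in 7 of 11 cases and rose in 1 (the same numbers adjusted over the list alone; adjusted p = 0.326 with an estimated correlation). Naive and memory T cell genes fell in 6 of 10 and rose in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.284 with an estimated correlation). H2-Ob and Cd74 stood at 0.781% and 0.632%, and Lef1 and Tcf7 at 0.902% and 0.915%, of their level in their highest class, and the B cell-like share fell with tumor. Proliferation genes fell in 3 of 18 cases, also when adjusted over the list alone (adjusted p = 0.507 with an estimated correlation). The proliferation call was lost without untreated tumor-free library 2 (adjusted p = 0.0524, camera) or untreated tumor-bearing library 2 (adjusted p = 0.0554, camera).

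In classical monocyte-like cells as a class, Cx3cr1, the fractalkine receptor of patrolling monocytes (ENSMUSG00000052336, mm10 chromosome 9, 119901616 to 120069879), fell from 262 ± 9.14 to 52.7 ± 12.8 CPM with tumor. Vcan, the matrix proteoglycan versican (ENSMUSG00000021614, chromosome 13, 89655312 to 89742509), rose from 61.1 ± 1.05 to 462 ± 134 CPM, a log2 fold of 2.92 ± 0.22. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 1658 of 11686 genes, 894 upward, with an adjusted p = 2.39e-06 for Cx3cr1 and 2.29e-04 for Vcan. The count was 510 without untreated tumor-free library 1, 630 without library 2 and 770 at resolution 2. Cluster 9.0 held 83.5% of the class without tumor and cluster 15 held 74.5% of it with tumor.

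Type I interferon response genes fell in 8 of 19 cases in classical monocyte-like cells (11 adjusted over the list alone; adjusted p = 0.298 with an estimated correlation). The antiviral gene Rsad2 fell from 96.6 ± 24.1 to 18.9 ± 1.31 CPM. Costimulation genes fell in 3 of 13 cases (2 rises and 5 falls adjusted over the list alone; adjusted p = 0.206 with an estimated correlation), and the maturation marker gene Cd83 fell from 291 ± 45.9 to 48.4 ± 3.87 CPM. Glycolysis genes rose in 8 of 14 cases and fell in 1 (9 and 2 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation). Dissociation stress genes fell in 8 of 15 cases and rose in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.220 with an estimated correlation). Niche genes rose in 3 of 16 cases (6 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation), with Mmp9 at 0.535% of its neutrophil-like level. S100a8 went from 0.562 and 1.11 to 25.6 and 15.7 UMIs per cell. With tumor its S100a9 to S100a8 ratio was 0.49 and 0.547, against 0.744 and 0.875 in neutrophil-like cells, which argues against neutrophil RNA alone. Naive and memory T cell genes fell in 5 of 10 and rose in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.284 with an estimated correlation), and cytotoxic genes fell in 2 of 16 and rose in 1 (3 and 1 adjusted over the list alone; adjusted p = 0.393 with an estimated correlation). The 5 naive and memory genes that fell stood at 0.16% to 1.73% of their highest class, and the B cell-like share fell too. The cytotoxic falls were Cx3cr1 and Zeb2 and the rise was Ccl4, at 0.512% of its highest class. Interferon gamma response genes rose in 2 of 25 cases, also when adjusted over the list alone (adjusted p = 0.634 with an estimated correlation), a call lost without untreated tumor-bearing library 2 (adjusted p = 0.858, camera). Among them was Iigp1 (3.10 ± 0.45), whose call was lost per animal (3.13) or at resolution 2 (1.10).

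Alveolar macrophage-like and endothelial cell-like cells changed in fewer genes. Fkbp5, a glucocorticoid-induced cochaperone, rose in alveolar macrophage-like cells from 34.1 ± 1.69 to 112 ± 23.6 CPM, a call lost when cells were summed per animal (1.69). Zbtb16, a transcription factor gene also induced by glucocorticoids (ENSMUSG00000066687, mm10 chromosome 9, 48654297 to 48836222), rose in endothelial cell-like cells from 25.7 ± 14.4 to 317 ± 66.2 CPM. Bcl2a1d, a survival gene of the BCL2 family with near-identical copies, fell in alveolar macrophage-like cells from 124 ± 14.5 to 64.3 ± 6.61 CPM. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 63 of 10251 genes in alveolar macrophage-like cells, 45 upward, and 109 of 6511 in endothelial cell-like cells, 92 upward. The adjusted p (edgeR) was 1.73e-05 for Fkbp5, 1.04e-04 for Bcl2a1d and 1.60e-09 for Zbtb16. The alveolar macrophage count was 20 without untreated tumor-free library 2. The endothelial count was 67 without untreated tumor-free library 1, 65 without untreated tumor-bearing library 1 and 18 without untreated tumor-bearing library 2. Kept doublets raised the alveolar macrophage count to 356.

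Interferon gamma response genes rose in 3 of 20 cases in alveolar macrophage-like cells (11 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation). In endothelial cell-like cells 3 of 22 rose (12 adjusted over the list alone; adjusted p = 0.352 with an estimated correlation), such as Igtp from 81.8 ± 0.396 to 352 ± 62.4 CPM. Type I interferon response genes rose in 1 of 17 cases in the first (2 adjusted over the list alone; adjusted p = 0.284 with an estimated correlation) and in 3 of 15 in the second (7 adjusted over the list alone; adjusted p = 0.220 with an estimated correlation). In endothelial cell-like cells, S100a8 averaged 0.299 and 4.16 UMIs per cell without and 29.7 and 46.3 with tumor. There myeloid suppression genes rose in 5 of 17 cases (9 rises and 1 fall adjusted over the list alone; adjusted p = 0.206 with an estimated correlation). Niche genes rose in 3 of 12 and granule genes in 2 of 6 (the same numbers adjusted over the list alone; adjusted p = 0.206 with an estimated correlation for both). Wfdc17 stood at 5.60% of its neutrophil-like level. In alveolar macrophage-like cells, where S100a8 went from 3.44 and 2.97 to 45.8 and 26.2 UMIs per cell, suppression genes rose in 1 of 17 cases and granule genes in 1 of 11 (the same numbers adjusted over the list alone; adjusted p = 0.295 and 0.284 with an estimated correlation). The other 12 lists that camera called in these classes had at most 1 member past the threshold in each direction. Camera called hemoglobin genes upward in T, NK, classical monocyte, neutrophil and alveolar macrophage-like cells, with 0 members past the threshold (adjusted p = 0.336, 0.298, 0.371, 0.326 and 0.316 with an estimated correlation). With no low-count filter the call was lost in NK (adjusted p = 0.0582, camera) and classical monocyte-like cells (adjusted p = 0.0894, camera). Hemoglobin genes took at most 0.002% of the UMIs of each class in the untreated tumor-free libraries. In untreated tumor-bearing libraries 1 and 2 they took 0.069% and 0.006% in T, 0.012% and 0.004% in NK, 0.132% and 0.003% in classical monocyte, 0.012% and 0.004% in neutrophil and 0.008% and 0.002% in alveolar macrophage-like cells. Camera also called surfactant and secretory genes upward in alveolar macrophage-like (1 of 5 adjusted over the list alone, adjusted p = 0.322 with an estimated correlation) and endothelial cell-like cells (adjusted p = 0.316 with an estimated correlation). These calls were lost without untreated tumor-bearing library 1 in the first (adjusted p = 0.695, camera) and library 2 in the second (adjusted p = 0.254, camera). Genes of alternative macrophage activation were called in none of the 6 classes by camera.

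Over the 6 classes, camera at the preset correlation called 67 of 111 list tests for the tumor, 47 upward and 20 downward. With an estimated correlation camera called 0, with 20 at an unadjusted p under 0.05, and fry called 1 (glycolysis in classical monocyte-like cells), so each list is described by its members.

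No class passed the test of shares for IL12-GEMys in tumor-bearing lungs. Neutrophil-like cells made up 33.5% ± 5.15 of treated and 34.9% ± 6.31 of untreated cells (n = 2 libraries each). Classical monocyte-like cells made up 11.3% ± 1.73 of treated cells, T cell-like cells 13.5% ± 1.12 and 12.6% ± 0.931, and NK cell-like cells 8.57% ± 1.47 and 7.08% ± 0.645. Plasmacytoid dendritic cell-like cells had the smallest p, with a log2 change of -1.36 ± 0.38 (adjusted p = 0.244, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Of 22 classes, 0 passed this edgeR test and 3 had an unadjusted p under 0.05. Without treated tumor-bearing library 2 the erythroid-like share passed (3.88, adjusted p = 0.00213, edgeR), as that class made up 3.57% of cells in treated tumor-bearing library 1.

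Classical monocyte-like cells of treated tumor-bearing lungs rose in interferon gamma targets. Iigp1, an immunity-related GTPase (ENSMUSG00000054072, mm10 chromosome 18, 60376027 to 60392634), rose from 6.55 ± 1.48 to 328 ± 38.7 CPM, a log2 fold of 5.66 ± 0.17. The guanylate-binding protein gene Gbp8 rose from 3.06 to 46.4 ± 9.62 CPM. Cx3cr1 fell further at -2.26 ± 0.16 on the log2 scale. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 1535 of 11686 genes changed, 854 upward. The adjusted p (edgeR) was 3.49e-11 for Iigp1, 2.35e-08 for Gbp8 and 3.92e-06 for Cx3cr1. The count was 629 without untreated tumor-bearing library 1. Cluster 6 held 93.0% of the class after treatment against cluster 15 with 74.5% before.

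Of 25 interferon gamma response genes 21 rose in classical monocyte-like cells (22 adjusted over the list alone; adjusted p = 0.125 with an estimated correlation). All 17 MHC class I genes rose (17 adjusted over the list alone; adjusted p = 0.131 with an estimated correlation). MHC class II genes rose in 7 of 11 cases (11 adjusted over the list alone; adjusted p = 0.125 with an estimated correlation), and H2-Ab1 went from 190 ± 68.0 to 890 ± 152 CPM. Type I interferon response genes rose in 10 of 19 cases and fell in 1 (13 and 1 adjusted over the list alone; adjusted p = 0.275 with an estimated correlation). Costimulation genes rose in 4 of 13 cases and fell in 1 (the same numbers adjusted over the list alone; adjusted p = 0.257 with an estimated correlation). Myeloid suppression genes fell in 4 of 20 cases and rose in 2 (the same numbers adjusted over the list alone; adjusted p = 0.275 with an estimated correlation). The lectin receptor gene Clec4d fell at -1.02 ± 0.13, while Cd274, which encodes PD-L1, rose at 2.23 ± 0.22. That call was lost without untreated tumor-bearing library 2 (adjusted p = 0.0705, camera) or treated tumor-bearing library 2 (adjusted p = 0.107, camera). Glycolysis genes rose in 9 of 14 and fell in 1 (10 and 2 adjusted over the list alone; adjusted p = 0.173 with an estimated correlation), and proliferation genes rose in 5 of 18 (13 and 1 fall adjusted over the list alone; adjusted p = 0.422 with an estimated correlation). Cytotoxic genes rose in 6 of 16, at 0.375% to 7.08% of their highest class, and fell in 1 (9 and 2 adjusted over the list alone; adjusted p = 0.382 with an estimated correlation), and granule genes rose in 2 of 14 and fell in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.382 with an estimated correlation). Interleukin-12 and interleukin-18 signalling genes rose in 5 of 12 and fell in 1 (the same numbers adjusted over the list alone; adjusted p = 0.224 with an estimated correlation). The signalling call was lost without untreated tumor-bearing library 2 (adjusted p = 0.0513, camera).

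Neutrophil-like cells of treated tumor-bearing lungs also rose in interferon-inducible genes. Gbp5 (ENSMUSG00000105504, mm10 chromosome 3, 142493978 to 142522344), which acts in inflammasome assembly, rose from 8.18 ± 2.22 to 92.5 ± 19.2 CPM. Ifi47 rose from 44.4 to 663 ± 292 CPM. Cd101, a marker of mature neutrophils, fell from 33.8 to 9.23 CPM. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 1306 of 10595 genes, 797 upward. The adjusted p (edgeR) was 1.72e-10 for Gbp5, 5.84e-08 for Ifi47 and 2.62e-05 for Cd101. The count was 719 without untreated tumor-bearing library 1, 633 without library 2 and 849 without treated tumor-bearing library 1. Cluster 3 held 68.2% of the class after treatment and cluster 2 held 81.6% before.

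Secondary granule genes rose after treatment, while cluster 8, which Ltf and Ngp help define, held 10.7% of neutrophil-like cells without tumor, 5.8% with tumor and 24.5% after treatment. Ngp rose from 2438 ± 186 to 8490 ± 817 CPM, Camp from 1170 ± 406 to 3040 ± 849 CPM and Ltf at 1.35 ± 0.27. Of 11 granule genes 7 rose (10 adjusted over the list alone; adjusted p = 0.221 with an estimated correlation). Of 25 interferon gamma response genes 20 rose (21 adjusted over the list alone; adjusted p = 0.0976 with an estimated correlation), and all 17 MHC class I genes rose (17 adjusted over the list alone; adjusted p = 0.125 with an estimated correlation). Of 18 type I interferon response genes 15 rose (17 adjusted over the list alone; adjusted p = 0.194 with an estimated correlation). Cd274 rose from 36.9 ± 1.84 to 194 ± 69.3 CPM. Cytotoxic genes rose in 10 of 17 cases (12 and 1 fall adjusted over the list alone; adjusted p = 0.216 with an estimated correlation). Proliferation genes rose in 10 of 18 (15 adjusted over the list alone; adjusted p = 0.275 with an estimated correlation) and MHC class II genes in 4 of 11 (7 adjusted over the list alone; adjusted p = 0.462 with an estimated correlation). The members of these 3 lists that rose stood at 0.471% to 1.42%, 1.07% to 3.18% and 0.631% to 8.89% of their highest class. TNF and NF-kB targets fell in 2 of 14 cases (3 adjusted over the list alone; adjusted p = 0.257 with an estimated correlation), with the feedback inhibitor gene Tnfaip3 at -1.22 ± 0.17. Their call was lost without untreated tumor-bearing library 2 (adjusted p = 0.0627, camera). Dissociation stress genes fell in 2 of 15 and rose in 1 (3 and 1 adjusted over the list alone; adjusted p = 0.521 with an estimated correlation). The stress call was lost without untreated tumor-bearing library 2 (adjusted p = 0.0749, camera) or treated tumor-bearing library 1 (adjusted p = 0.136, camera). Alternative activation genes rose in 1 of 5 (3 adjusted over the list alone; adjusted p = 0.393 with an estimated correlation), a call of the list lost without treated tumor-bearing library 1 (adjusted p = 0.105, camera).

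The genes of the chemokine Xcl1 and of interferon gamma rose in T cell-like cells of treated tumor-bearing lungs. Xcl1 (ENSMUSG00000026573, mm10 chromosome 1, 164931644 to 164935527) rose from 6.52 ± 0.912 to 135 ± 12.5 CPM, a log2 fold of 4.38 ± 0.16. Furin, a proprotein convertase induced by interleukin-12, rose from 44.3 ± 6.04 to 425 ± 74.8 CPM. Ifng, the interferon gamma gene (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), rose from 83.5 ± 38.2 to 1046 ± 221 CPM, a call lost without treated tumor-bearing library 1 (adjusted p = 0.0698, edgeR). The fatty acid elongase gene Elovl6 fell from 72.8 ± 8.67 to 29.1 ± 3.20 CPM. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 3432 of 11557 genes changed, 1962 upward. The adjusted p (edgeR) was 8.97e-10 for Xcl1, 7.02e-08 for Furin, 0.0124 for Ifng and 1.15e-05 for Elovl6. The count was 1975 without treated tumor-bearing library 1. Clusters 30 and 12.5, both partly defined by Ifng, held 0.3% and 0.5% of the class before and 7.7% and 4.1% after treatment, and cluster 23 went from 5.3% to 12.2%.

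Of 23 interferon gamma response genes 20 rose in T cell-like cells (22 adjusted over the list alone; adjusted p = 0.152 with an estimated correlation), with Gbp2 from 62.9 ± 5.47 to 403 ± 31.1 CPM. Proliferation genes rose in 16 of 18 cases (18 adjusted over the list alone; adjusted p = 0.257 with an estimated correlation). Glycolysis genes rose in 11 of 14, also when adjusted over the list alone (adjusted p = 0.125 with an estimated correlation). Naive and memory genes fell in 6 of 10 cases (7 adjusted over the list alone; adjusted p = 0.382 with an estimated correlation). The transcription factor gene Tcf7 fell from 444 ± 14.3 to 201 ± 48.5 CPM. Cytotoxic effector genes rose in 6 of 17 cases, also when adjusted over the list alone (adjusted p = 0.495 with an estimated correlation). MHC class I genes rose in 10 of 17 cases, also when adjusted over the list alone (adjusted p = 0.240 with an estimated correlation). Of 19 type I interferon response genes 9 rose (11 adjusted over the list alone; adjusted p = 0.382 with an estimated correlation). Interleukin-12 and interleukin-18 signalling genes rose in 3 of 12 cases and fell in 1 (the same numbers adjusted over the list alone; adjusted p = 0.513 with an estimated correlation). This list's call was lost without untreated tumor-bearing library 2 (adjusted p = 0.0968, camera) or treated tumor-bearing library 1 (adjusted p = 0.104, camera). Of the alternative activation list, 2 of 7 genes rose (2 adjusted over the list alone; adjusted p = 0.462 with an estimated correlation). Its call was lost without untreated tumor-bearing library 2 (adjusted p = 0.0555, camera) or treated tumor-bearing library 1 (adjusted p = 0.108, camera).

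NK cell-like cells had the highest count of changed genes of the 6 classes, 4938 of 10652 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 2643 of them upward. Ly6a, which encodes Sca-1 (ENSMUSG00000075602, mm10 chromosome 15, 74994877 to 74998031), rose from 19.9 ± 5.68 to 1528 ± 25.6 CPM, a log2 fold of 6.28 ± 0.13 (adjusted p = 2.31e-20, edgeR). Il10, an immunoregulatory cytokine gene (ENSMUSG00000016529, chromosome 1, 131019845 to 131024974), had 1 UMI in untreated and 1999 UMIs in treated libraries, where it reached 139 ± 13.3 CPM. The ratio was 614 with a 95% counting interval of 110 to 24250. Ifng rose from 295 ± 8.60 to 2013 ± 44.5 CPM (adjusted p = 5.59e-04, edgeR). Phactr3 fell from 51.6 to 8.96 ± 2.68 CPM (adjusted p = 8.26e-11, edgeR). The median UMI count per NK cell-like cell was 2917 and 3435 in untreated and 4947 and 6374 in treated tumor-bearing libraries. Cluster 21, which Il10 also helps define, held 3.2% of the class before and 25.1% after treatment.

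All 18 proliferation genes rose in NK cell-like cells (18 adjusted over the list alone; adjusted p = 0.139 with an estimated correlation). Top2a rose from 107 ± 4.50 to 534 ± 48.4 CPM. Inhibitory receptors rose in 5 of 8 cases, also when adjusted over the list alone (adjusted p = 0.216 with an estimated correlation), with Lag3 from 4.54 ± 0.689 to 55.9 ± 4.32 CPM. Glycolysis genes rose in 10 of 14 cases and fell in 2 (the same numbers adjusted over the list alone; adjusted p = 0.125 with an estimated correlation). Of 19 interferon gamma response genes 13 rose, also when adjusted over the list alone (adjusted p = 0.125 with an estimated correlation). Type I interferon genes rose in 8 of 18 cases and fell in 1 (the same numbers adjusted over the list alone; adjusted p = 0.425 with an estimated correlation), and MHC class I genes rose in 12 of 17, also when adjusted over the list alone (adjusted p = 0.382 with an estimated correlation). Dissociation stress genes rose in 9 of 15 and fell in 1 (the same numbers adjusted over the list alone; adjusted p = 0.382 with an estimated correlation). The cytotoxic list was not called, with 7 rises and 4 falls among 17 genes. The signalling list was not called either. Stat4, the transcription factor of the interleukin-12 receptor, fell at -0.99 ± 0.10, Il12rb2 at -0.64 ± 0.10 and Ifngr1 at -0.92 ± 0.09.

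Interferon gamma targets rose in alveolar macrophage-like and endothelial cell-like cells after treatment. In alveolar macrophage-like cells Gbp2 (ENSMUSG00000028270, mm10 chromosome 3, 142620602 to 142638008) rose from 58.0 ± 12.5 to 383 ± 80.3 CPM. In endothelial cell-like cells Ido1, a tryptophan-degrading enzyme (ENSMUSG00000031551, chromosome 8, 24584136 to 24597009), rose from 10.7 ± 1.47 to 222 ± 78.7 CPM, and Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095) from 27.1 ± 24.7 to 433 ± 124 CPM. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 417 genes in alveolar macrophage-like cells, 283 upward, and 92 in endothelial cell-like cells, 74 upward. The adjusted p (edgeR) was 6.56e-04 for Gbp2, 7.67e-08 for Ido1 and 2.10e-08 for Cd274. The first count was 185 without untreated tumor-bearing library 1, 274 without treated library 1 and 206 without treated library 2. The second was 45 without untreated tumor-bearing library 1, 29 without untreated library 2 and 153 without treated library 2.

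Interferon gamma response genes rose in 14 of 20 cases in alveolar macrophage-like cells (18 adjusted over the list alone; adjusted p = 0.0839 with an estimated correlation) and in 17 of 22 in endothelial cell-like cells (19 adjusted over the list alone; adjusted p = 0.125 with an estimated correlation). MHC class I genes rose in 13 of 17 (17 adjusted over the list alone; adjusted p = 0.0976 with an estimated correlation) and 11 of 17 cases (14 adjusted over the list alone; adjusted p = 0.125 with an estimated correlation). Type I interferon genes rose in 4 of 17 (9 adjusted over the list alone; adjusted p = 0.243 with an estimated correlation) and 5 of 15 (13 adjusted over the list alone; adjusted p = 0.125 with an estimated correlation). MHC class II genes rose in 1 of 11 (2 adjusted over the list alone; adjusted p = 0.469 with an estimated correlation) and 4 of 11 (7 adjusted over the list alone; adjusted p = 0.221 with an estimated correlation). Cytotoxic genes rose in 9 of 15 cases in alveolar macrophage-like cells (11 adjusted over the list alone; adjusted p = 0.0976 with an estimated correlation) and signalling genes in 3 of 11 (also 3 adjusted over the list alone; adjusted p = 0.125 with an estimated correlation). The 9 cytotoxic genes stood at 1.05% to 2.37% of their highest class. Granule genes rose there in 3 of 11 cases (4 adjusted over the list alone; adjusted p = 0.216 with an estimated correlation). Glycolysis genes rose in 2 of 13 (5 adjusted over the list alone; adjusted p = 0.275 with an estimated correlation), which camera did not call without untreated tumor-bearing library 2 (adjusted p = 0.0719). The 7 called lists of T, alveolar macrophage and endothelial cell-like cells not described had at most 1 member past the threshold. In all, camera at the preset correlation called 56 of 111 list tests for the treatment, 51 upward. With an estimated correlation camera called 0, with 24 at an unadjusted p under 0.05, and fry called 27.

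**Figure D2:**
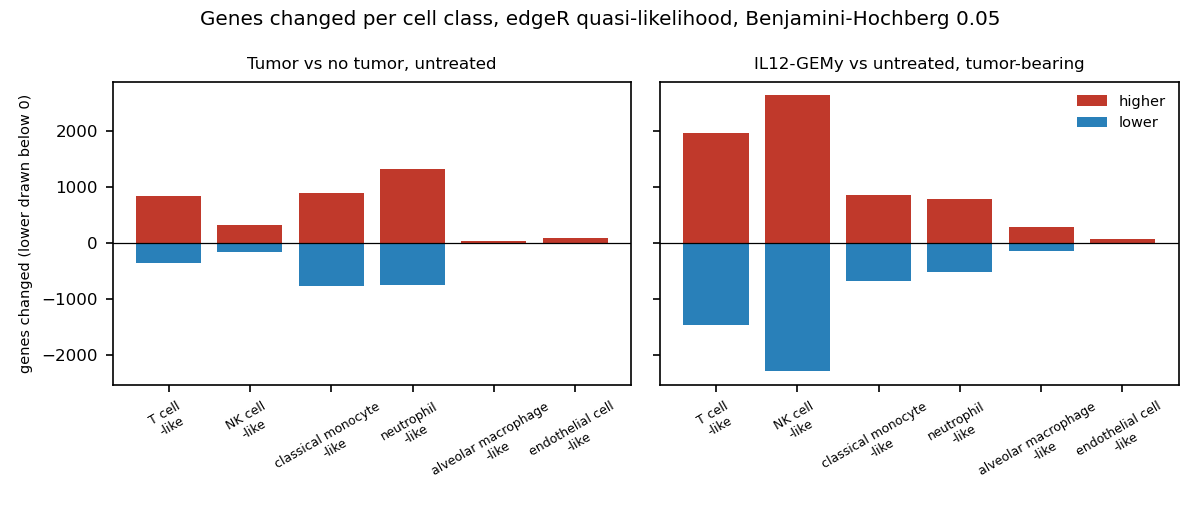
Number of genes past the edgeR quasi-likelihood test at a Benjamini-Hochberg threshold of 0.05 in 6 cell classes, with genes higher in the first-named group drawn above 0 and lower ones below. In neutrophil-like cells 2072 genes passed for the tumor, and in NK cell-like cells 4938 for the treatment.

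**Figure D3:**
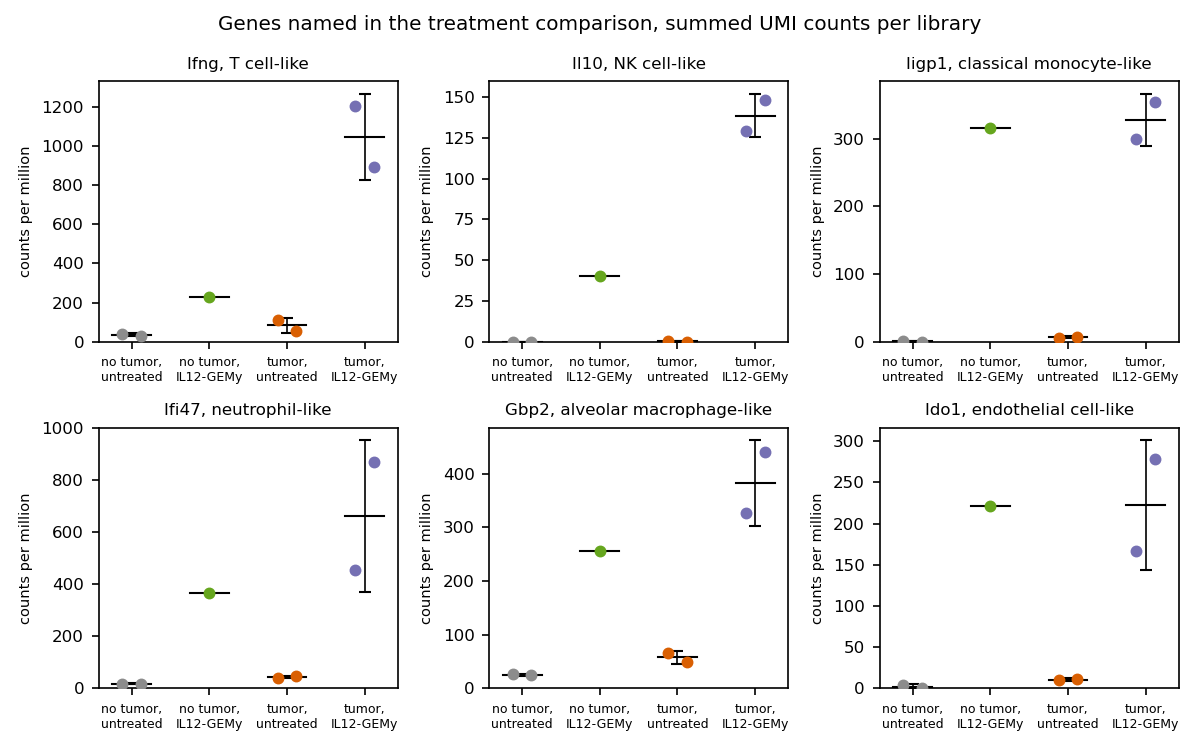
Level of 6 genes in CPM of a class's summed UMIs for each library (points), with mean (line) and SD (error bar) per group. Iigp1 in classical monocyte-like cells lies at 328 CPM on average in treated tumor-bearing libraries, against 6.55 CPM in untreated ones.

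Without a tumor, the treated library also stood above the untreated ones in interferon gamma response genes. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment assumes here that the single library varies like the others. By it 21 of 25 of these genes rose in classical monocyte-like cells (23 adjusted over the list alone), 21 of 23 in T cell-like cells (22 adjusted over the list alone) and 16 of 25 in neutrophil-like cells (20 adjusted over the list alone). They rose in 16 of 22 cases in endothelial cell-like cells (19 adjusted over the list alone), 12 of 20 in alveolar macrophage-like cells (16 adjusted over the list alone) and 10 of 19 in NK cell-like cells, with 1 fall (11 and 3 adjusted over the list alone). The camera adjusted p was 0.0947, 0.0932, 0.0904, 0.0947, 0.0932 and 0.158 with an estimated correlation, in the order of these classes. Cluster 9.0 held 83.5% of classical monocyte-like cells in the untreated libraries and cluster 6 held 99.0% in the treated one. All 18 proliferation genes rose in NK cell-like cells (18 adjusted over the list alone; adjusted p = 0.0994 with an estimated correlation), while cluster 21 went from 0.6% to 14.0% of the class and the median UMI count per cell from 2329 and 2733 to 5301. The classical monocyte-like share was 15.4% in the treated library, against 3.96% ± 0.350 in untreated ones (log2 change 1.96 ± 0.35, adjusted p = 0.0253, edgeR). Of the 30 genes named for the treatment with tumor, 20 also changed in the same direction without tumor. Camera called 52 of 111 list tests at the preset correlation and 0 with an estimated one (27 at an unadjusted p under 0.05), while fry called 25. For alternative activation genes in alveolar macrophage-like cells (median -0.10, mean 0.03) and suppression genes in endothelial cell-like cells (median -0.15, mean 0.27) the median lay below 0 while the mean and the test pointed upward.

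The difference between the treatment effects with and without tumor was tested for named genes and lists. It passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment for 5 of the 30 genes named for the treatment. These were Elovl6 in T cell-like cells (-1.92, adjusted p = 0.00387, edgeR), Ly6a (1.10, adjusted p = 0.0207) and Phactr3 (-1.31, adjusted p = 0.00763) in NK cell-like cells, Iigp1 in classical monocyte-like cells (-3.05, adjusted p = 0.0119) and Gbp5 in neutrophil-like cells (-3.19, adjusted p = 0.0157). Iigp1 reached 316 CPM in the treated tumor-free library and 328 ± 38.7 in treated tumor-bearing ones, from 0.747 and 6.55 ± 1.48 CPM untreated. The count was 2 without either untreated tumor-free library and 8 without treated tumor-bearing library 2. Without untreated tumor-free library 1, the calls of Iigp1 (-4.04), Phactr3 (-1.22) and Ly6a (1.17) were lost, and without library 2 those of Iigp1 (-2.46), Gbp5 (-2.82) and Ly6a (1.04). Ly6a also lost its call without untreated tumor-bearing library 2 (0.82), treated tumor-bearing library 1 (1.09) or library 2 (1.11), and Phactr3 without the last (-1.06). Summed per animal, none of the 5 calls held (Elovl6 -1.89, adjusted p = 0.092, edgeR). Interferon gamma response lists had a median difference of -0.56 in T, -0.80 in classical monocyte, -1.50 in neutrophil, -0.25 in alveolar macrophage and -0.93 in endothelial cell-like cells and of 0.48 in NK cell-like cells. The camera adjusted p was 0.382, 0.409, 0.296, 0.492, 0.471 and 0.296 with an estimated correlation. In the first 5 classes 0 of 23, 1 of 25, 3 of 25, 0 of 20 and 1 of 22 members passed downward, and in NK cell-like cells 0 of 19 passed (10, 8, 11, 2 and 2 downward and 3 upward adjusted over the list alone). Camera at the preset correlation called 51 of 111 list tests for this difference, 21 upward. With an estimated correlation camera called 0 and fry called 0, and 12 passed an unadjusted p of 0.05 in each. The monocyte share had a difference of -1.92 ± 0.46 (adjusted p = 0.119, edgeR).

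Treated tumor-bearing lungs were also compared with untreated tumor-free ones. Of the genes called for the tumor, 1140 of 1194 in T cell-like, 454 of 486 in NK cell-like and 1438 of 1658 in classical monocyte-like cells were called in the same direction there. The same held for 1596 of 2072 in neutrophil-like, 54 of 63 in alveolar macrophage-like and 72 of 109 in endothelial cell-like cells. Independent lists would share 318, 145, 269, 304, 3 and 4 genes in the order of these classes. In 10 simulations per class with both groups set equal at most 3 genes were called in both. They called a mean of only 0.5 to 2 genes between the groups, so the part due to the shared tumor-free libraries stays open. The tumor and treatment comparisons share the untreated tumor-bearing libraries with opposite signs. Across genes, which are not independent replicates, their log2 folds correlated at 0.114 in T cell-like cells, against -0.58 in 20 simulations of unchanged groups. In neutrophil-like cells the correlation was -0.055 against -0.244. The covariances were 0.048 against -0.055 and -0.04 against -0.073. Genes higher with tumor and higher again after treatment numbered 482 in T cell-like cells, where independent lists would share 143. Neither value leaves out both the shared libraries and the effects.

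Of the genes given in every case, Cd274 rose with treatment in T, classical monocyte, neutrophil and endothelial cell-like cells, not in alveolar macrophage-like (0.25, adjusted p = 0.386, edgeR) or NK cell-like cells (-0.07, adjusted p = 0.748, edgeR). Cxcl9, a chemokine gene induced by interferon gamma, passed for the treatment only in T cell-like cells (2.75, adjusted p = 0.0425, edgeR) at 1.26 CPM. S100a8 in T cell-like cells went from 110 to 1715 ± 924 CPM with tumor (adjusted p = 0.0405, edgeR). At least 98.5% of T, NK and B cell-like cells of each tumor-bearing library held an S100a8 UMI, against 17.4% to 40.6% without tumor. Arg1, Il12a and Il12b passed in neither main comparison. Il12b was called in classical monocyte-like cells for the treatment without tumor (adjusted p = 4.21e-05, edgeR). In the treated library 6 of 1451 cells held all 166 UMIs and 1 cell held 150 of them, against 0 UMIs in the untreated tumor-free libraries. Markers of the rhabdomyosarcoma had 2, 5, 8 and 5 UMIs in the tumor-bearing libraries and 6, 8 and 1 in the tumor-free ones. Tumor cells were not detectable above background at this depth.

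**Figure D4:**
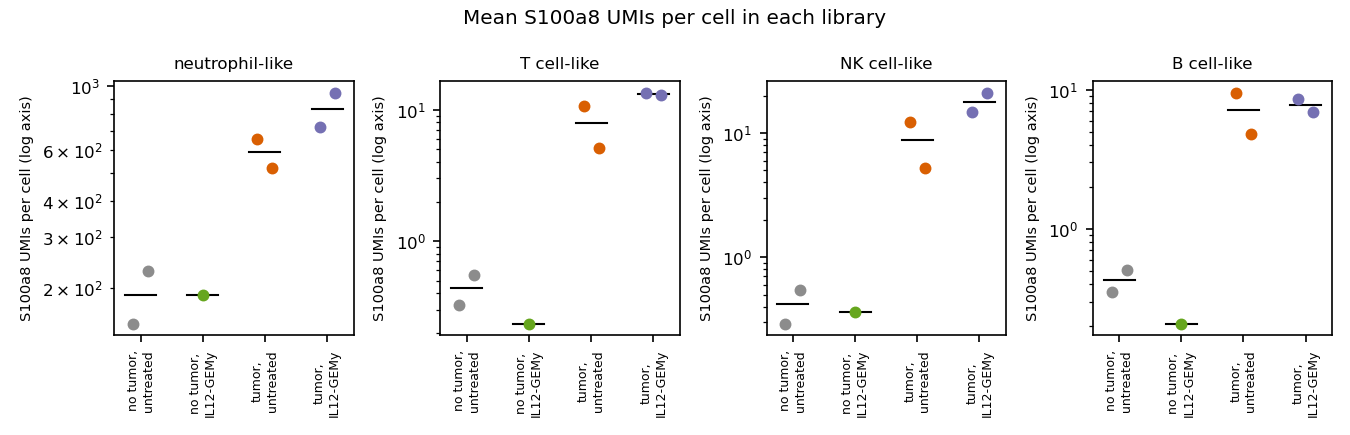
Mean S100a8 UMIs per cell (log axis) in neutrophil, T, NK and B cell-like cells of each library (points), with the group mean (line). In tumor-bearing libraries the lymphoid classes lie between 4.79 and 21.0 UMIs per cell, and in tumor-free ones between 0.208 and 0.552.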

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

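The tests of a higher starting level, of the single treated tumor-free library, of the rise of neutrophils and of free RNA library by library and against depth were chosen only after the result was seen.

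Camera at the preset correlation called the interferon gamma response list downward, for the treatment effect with tumor less that without, in 5 of 6 classes, not in NK cell-like cells, but 0 to 3 of its 20 to 25 members passed in each of the 5, and 0 of these calls held with an estimated correlation (adjusted p = 0.296 to 0.492) or by fry. Iigp1 in classical monocyte-like cells differed by -3.05 and Gbp5 in neutrophil-like cells by -3.19 on the log2 scale, calls lost per animal (-2.97 and -2.89), without untreated tumor-free library 2 (-2.46 and -2.82) and, for Iigp1, without library 1 (-4.04) or at resolution 2 (-1.04). A higher level before treatment in tumor-bearing mice would leave both treated groups alike, and the list's median between treated mice with and without tumor was -0.57 in classical monocyte, -0.26 in T, -0.20 in neutrophil, 0.35 in alveolar macrophage and 0.06 in endothelial cell-like cells. As the treated tumor-free group has 1 library, these medians have no spread between libraries, and a higher starting level and a property of that library cannot be told apart from an effect of the tumor on the response, which stays open as a hypothesis.

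Neutrophil transcripts stood in T, NK and B cell-like cells of tumor-bearing lungs, where at least 98.5% of these cells of each library held an S100a8 UMI, which argues against doublets. The ratio of S100a9 to S100a8 UMIs lay within 1.09 times that of neutrophil-like cells, within the bound of 1.5 that free RNA of neutrophils needs. Between the lymphoid classes S100a8 UMIs per cell differed by 1.31 and 1.09 times in untreated tumor-bearing libraries. In treated ones this was 1.71 and 3.05 times, past the preset bound of 2 in 1 of 4. There B cell-like cells held 6.88 S100a8 UMIs, and NK cell-like cells 21.0 at 2.47 times the median depth, which the bound ignores. In untreated library 1 T cell-like cells were deeper than NK cell-like ones but held less S100a8, so depth does not settle it. Free RNA stays open in the libraries within the bound. No biological explanation was tested.

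The lower B cell-like share with tumor was set against a rise of neutrophils in a fixed total. Among cells other than neutrophils the share still changed by -1.17 ± 0.29 (log2, adjusted p = 0.0425, edgeR), which argues against that rise as the whole account. The share of all barcodes with Cd79a and Ms4a1 UMIs changed by -1.60, from 32.2% and 35.8% to 8.46% and 14.0%, which argues against cells lost at the mitochondrial limit. Uneven recovery of B cells from the tissue and an effect of the tumor on B cells were not tested, as the values are shares and not counts per lung.

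Further treatment effects differed with tumor by the edgeR interaction test with Benjamini-Hochberg adjustment, and all rest on 1 treated tumor-free library, whose own properties were not separated from its group. Elovl6 in T cell-like cells differed by -1.92 and Emb in NK cell-like cells by 1.37, and both calls held with each library left out, but Elovl6 not per animal (-1.89). Hmmr in NK cell-like cells differed by -2.48 (adjusted p = 0.0134, edgeR), a call lost without untreated tumor-free library 1 (-3.89) or 2 (-1.87), per animal (-2.39) and in DESeq2 (-2.53). Tk1 there differed by -2.29 (adjusted p = 0.00199, edgeR), a call lost without untreated tumor-free library 1 (adjusted p = 0.0681, edgeR). Ly6a there differed by 1.10, and only without untreated tumor-bearing library 1 was its call kept (0.82 to 1.17 without the others), and it was lost per animal (1.32) and under the strict cell filter (1.06). Phactr3 there differed by -1.31, a call lost without untreated tumor-free library 1 (-1.22) or treated tumor-bearing library 2 (-1.06), per animal (-1.32) and in DESeq2 (-1.33). Zbtb16 in endothelial cell-like cells differed by -3.27 (adjusted p = 2.89e-04, edgeR), a call lost without untreated tumor-bearing library 2 (-2.98) and in DESeq2 (-3.23). Il12b in classical monocyte-like cells had a fitted difference of -13.51 (adjusted p = 0.0221, edgeR), no bound because untreated tumor-free libraries held 0 UMIs, and lost its call without either untreated tumor-free (-13.82 for both) or untreated tumor-bearing library (-13.01 and -13.73). Camera called 51 of 111 list tests for this difference, 0 with an estimated correlation.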

How the results depend on the processing

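None of the alternatives was chosen after the data were seen. Of values for the 30 genes named for the tumor, 336 of 375 kept their direction and side of the threshold and 39 lost the call. For the treatment these numbers were 353 of 378 and 25, and 17 and 22 of the 30 genes kept their call in every setting run. In the 6 further classes 318 of 363 gene values for the tumor and 304 of 356 for the treatment kept their call. Of values for lists called for the tumor 376 of 536 kept their call, and for the treatment 329 of 448. Of 228 share values 216 kept their side for the tumor, with 4 calls lost and 8 gained, and 224 for the treatment, with 4 gained. Of 137 values for the 10 genes whose treatment effects differed with tumor 108 kept their call. No called gene or share changed its sign. List calls turned in 3 cases: TNF and NF-kB targets in alveolar macrophage-like cells for the tumor without untreated tumor-free library 2 (camera adjusted p = 1.89e-05 to 0.917 with each library left out, the last in this case), and for the treatment the cytotoxic list in endothelial cell-like cells without treated tumor-bearing library 1 (camera adjusted p = 1.37e-32 to 0.651) and the niche list in alveolar macrophage-like cells without library 2 (camera adjusted p = 4.17e-08 to 0.767). The cause was not tested where no cause is named here.

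Genes called with edgeR for the tumor numbered 1194 in T, 486 in NK, 1658 in classical monocyte, 2072 in neutrophil, 63 in alveolar macrophage and 109 in endothelial cell-like cells. DESeq2 called 743 in T (602 upward), 285 in NK (238 upward), 1344 in neutrophil, 54 in alveolar macrophage (48 upward) and 26 in endothelial cell-like cells (26 upward). With no low-count filter there were 243 in alveolar macrophage-like and 165 in endothelial cell-like cells, with only the 4 libraries compared 110 in alveolar macrophage-like cells, and with kept doublets 836 in NK cell-like and 356 in alveolar macrophage-like cells. Summed per animal there were 2125 in T cell-like and 35 in alveolar macrophage-like cells, and at resolution 2 there were 770 in classical monocyte-like cells. With each library left out, which assumes that the library left alone varies like the others and tests fewer samples, the counts ran from 384 to 1229, 139 to 1044, 510 to 1324, 1035 to 1691, 20 to 71 and 18 to 108 in the order given first.

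For the treatment with tumor edgeR called 3432, 4938, 1535, 1306, 417 and 92 genes in the same order. DESeq2 called 1869, 3247, 855, 544, 134 (111 upward) and 34 (32 upward). With no low-count filter there were 665 in alveolar macrophage-like cells, per animal 2349 in classical monocyte-like cells, and at resolution 2 there were 928 in classical monocyte-like and 268 in alveolar macrophage-like cells. With each library left out the counts ran from 1975 to 3498, 3686 to 4738, 629 to 1364, 633 to 1480, 185 to 370 and 29 to 153.

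Classes changed in share with tumor numbered 3, with 5 per animal, 5 under the strict cell filter and 1 to 3 with a library left out. For the treatment 0 classes passed, with 1 among immune classes only, 1 at resolution 2 and 0 to 1 with a library left out. Lists called numbered 67 for the tumor (0 with an estimated correlation, 1 by fry, 66 to 69 with a library left out) and 56 for the treatment (0, 27 and 52 to 64). Of genes named for the treatment 20 also changed without tumor (17 to 18 with a library left out), and 5 differed in their treatment effect (10 with no low-count filter, 8 with kept doublets, 2 to 8 with a library left out). Of genes named for the tumor 25 were also called between treated tumor-bearing and untreated tumor-free lungs (23 to 24 with a library left out).

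The animal numbers of the labels do not pair mice, so the fit with the replicate block shows only how counts move. The treated tumor-free library has animals 1 and 2 in the labels but hashtags 3 and 4, as the libraries of animals 3 and 4 have, so its place in the block goes against its hashtags. With the block the tumor counts were 1560, 700, 2009, 2008, 72 and 150 genes and the treatment counts 3793, 5099, 2020, 1330, 468 and 118. It gave 4 classes changed in share for the tumor and 1 for the treatment, 22 genes also changed without tumor, 10 that differed in their treatment effect and 24 of the genes named for the tumor. No value per animal could be had for endothelial cell-like, AT2 cell-like, basophil or mast cell-like and cDC2-like cells, and lists were not tested under the block, per animal, with doublets, the strict filter, resolution 2 or 4 libraries. Of the 6 main classes endothelial cell-like cells had the lowest recovery of simulated 2-fold changes (16.9% for the tumor), the fewest counts (from 104892 per library) and the highest biological coefficient of variation (0.205), so what depth limits there was not separated from spread.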

Other observations

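The gene groups described here were chosen after the results of all lists in the 6 further classes were seen, and so was the mean of Il12b without the highest cell, while the other test of Il12b was set before.

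Fkbp5 and Zbtb16 rose with tumor in further classes. Fkbp5 went from 8.28 ± 0.216 to 84.9 ± 1.72 CPM in nonclassical monocyte-like cells (log2 fold 3.35 ± 0.19, adjusted p = 3.97e-12, edgeR) and from 5.41 ± 2.83 to 68.7 ± 6.00 CPM in cDC2-like cells, conventional dendritic cells of type 2 (adjusted p = 9.15e-06, edgeR). Zbtb16 rose in AT2 cell-like cells, the surfactant-making epithelium, from 5.40 ± 2.76 to 54.9 ± 4.87 CPM (adjusted p = 4.51e-04, edgeR), a call lost without untreated tumor-free library 1 (adjusted p = 0.0633, edgeR). Hmgcs1, an enzyme of sterol synthesis, fell in cDC2-like cells from 219 ± 15.9 to 46.4 ± 13.5 CPM (adjusted p = 8.86e-08, edgeR) and S1pr1 in B cell-like cells from 187 ± 5.02 to 118 ± 1.30 CPM (adjusted p = 1.39e-04, edgeR). Cluster 20.4 held 47.0% of cDC2-like cells without and cluster 20.1 held 54.6% with tumor.

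IL12-GEMys raised interferon gamma response genes in tumor-bearing lungs also in nonclassical monocyte-like (22 of 24, 22 adjusted over the list alone), AT2 cell-like (13 of 19, 18 adjusted over the list alone) and cDC2-like cells (11 of 21, 13 adjusted over the list alone). Camera's call held in these 3 classes (adjusted p = 0.0167 with an estimated correlation). In B cell-like cells 19 of 23 rose (22 adjusted over the list alone; adjusted p = 0.0529 with an estimated correlation), with Ifi47 from 34.4 ± 6.04 to 228 ± 37.9 CPM, while cluster 0 held 78.6% of the class before and cluster 5 held 81.6% after treatment. All 17 MHC class I genes rose in nonclassical monocyte-like cells (17 adjusted over the list alone; adjusted p = 0.0234 with an estimated correlation), and Tap1 rose in AT2 cell-like cells from 29.6 ± 1.66 to 97.0 ± 1.53 CPM. Trem2, a lipid receptor gene of macrophages, fell in nonclassical monocyte-like cells from 37.0 ± 3.63 to 1.77 ± 0.963 CPM (adjusted p = 4.83e-11, edgeR). Cluster 13 held 65.4% of this class before and cluster 14 held 98.8% after treatment.

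Il12b UMIs in classical monocyte-like cells of the treated tumor-free library averaged 27.7 per cell with any, with 0 Il12a UMIs in those 6 cells, but 1 cell held 150 of the 166 UMIs and the other 5 averaged 3.2, so whether a few cells with a strong transcript were the source stays open. Migratory dendritic cell-like cells averaged 19.0 Il12b UMIs per cell with any there and 2.0 to 70.4 (260 of 563 UMIs in 1 cell) in the other libraries.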
